A study of Mus musculus with 2 samples.

How the data were processed

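MicroRNA sequencing was carried out on total RNA of the left cerebral cortex of female mice at postnatal day 10. The mice were first-generation hybrids of the laboratory strain C57BL/6J and the wild-derived strain CAST/EiJ, a cross sold as B6CASTF1/J. The labels give 1 group with 2 biological replicates, and they number the 2 females differently, so the replicates were taken as separate animals (animal 1 and animal 2), although both carry the same donor entry. Per the labels, libraries were made with a multiplexed microRNA protocol that selects short RNA.

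The deposited files hold whole-number read counts, 1 table per library. Per the notes beside each table, the build was mm10 and the annotation was release M21 of GENCODE; the aligner, the counter and their versions are not given in the sources used here. Each table lists 2202 microRNA genes, and all 2202 were found in the M21 annotation used here for symbols, coordinates and neighbouring genes. The unit is the hairpin gene, so reads of the 5′ and 3′ arms of a hairpin are summed. Each table has 3 columns of counts: reads on both strands, on the gene's own strand and on the opposite strand. A further 4 rows in each deposited table count reads that were unmapped, mapped to several positions, outside any listed gene, or on overlapping genes. These rows were left out of library sizes and tests.

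The own-strand counts were used, since they had the larger total of the strand columns. In animal 1, 3806078 reads were counted to microRNA genes, 33.5% of 11350270 reads. In animal 2, the number was 2602935 reads, 30.4% of 8551277. Unmapped reads made up 17.9% and 23.6% of all reads in animals 1 and 2, reads mapped to several positions 42.7% and 40.4%, and reads outside any listed gene 5.79% and 5.62%. On the own strand no read was ambiguous, while in the unstranded column 2.72% and 1.86% were, because 64 genes overlap a microRNA gene of the opposite strand. Reads that map to several positions stand in a row of their own, beside the reads counted to genes. With these rows, the own-strand and the unstranded column add up to the same total, 11350270 reads in animal 1 and 8551277 in animal 2. How the counting treated such reads otherwise is not given in the sources used here. Levels of microRNAs with several genomic copies are therefore uncertain and may be too low.

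CPM values (reads of a gene scaled to the usual common library size) and percentages were computed from the deposited counts over all reads counted to microRNA genes. A gene was called detected at 10 CPM or more in both libraries, which is 38.1 reads in animal 1 and 26.0 in animal 2. Shares of single libraries carry exact Clopper-Pearson 95% intervals, and a count of 0 allows up to 3 counts (a one-sided 95% limit), or 0.788 CPM in animal 1 and 1.15 CPM in animal 2. Reads had no molecular identifiers that the files show, so intervals and floors cover counting error only. Values over both animals are given as mean ± SD with n = 2, and such an SD rests on a single difference.

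Variation between the animals was estimated from the counts with edgeR 4.0.16 in R 4.3.3, using TMM factors (1.07 and 0.932), an intercept-only design and the 531 genes with at least 10 counts summed over both libraries. Genes were compared between the 2 libraries with an exact conditional binomial test given the TMM effective library sizes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. That test compares these 2 libraries and no conditions. Log2 ratios are animal 1 over animal 2 after TMM, with 0.5 added to each count, and their 95% intervals are exact. Agreement across genes used log2(CPM + 0.5). Detection in 19 gene lists was compared with that of all other microRNA genes by two-sided Fisher's exact tests, adjusted over the lists; genes of a cluster are not independent. Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3 was used for these steps.

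Both procedures were tested on simulated data. For the variation between the animals, simulated coefficients of variation of 10, 30 and 60% were recovered as 9.94, 30.1 and 59.2% on at least 507 genes. For the genes differing between the 2 libraries, 200 genes were changed in simulated counts that held counting noise only. On 530 genes the test called 53.1% of those changed 1.5-fold, 76.0% at 2-fold, 86.0% at 3-fold and 96.0% at 5-fold. Of the unchanged genes it called 1.21%. No variation between animals was simulated, so these shares cover counting noise and not the spread between the animals.

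The lists, the tests of the report, most alternatives and the rule for named genes were fixed before the data were examined; the exceptions are named with their values in the closing section. The rule names the 25 genes with the highest mean CPM, up to 4 members of each list by mean CPM, and the 5 genes highest in each library relative to the other by log2 ratio, among genes with at least 100 counts that passed the exact binomial test. Mir9 and Mir124 were singled out in advance as multi-copy examples. Multi-copy genes are those whose symbols differ only in the final copy number. Alternatives tried were the unstranded counts, other denominators, each animal alone, other thresholds and count minimums, DESeq2 1.42.0 size factors and dispersions, library totals without further scaling, and another pseudocount. No comparison between groups was possible, as the data hold 1 group.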

Results

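The data describe which microRNAs were present in the left cerebral cortex of 10-day-old female hybrid mice, and how far 2 animals differed. MicroRNAs are short RNAs, cut from hairpin transcripts, that repress messenger RNAs. The libraries held 3806078 reads counted to microRNA genes in animal 1 and 2602935 in animal 2. The libraries form a single group of 2 animals, so levels, detection and the spread between the animals are reported.

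Among reads counted to a microRNA gene, the let-7 family, the imprinted Dlk1-Dio3 region of chromosome 12 and a few single genes held the largest shares. Mirlet7b (ENSMUSG00000065564.1, chromosome 15, 85707319 to 85707403, mm10, in an exon annotated to Lncppara) took the largest share of counted reads, 7.74% ± 1.48 (SD, n = 2). Mir139 (chromosome 7, 101475376 to 101475443, in an intron of Gm45837) followed at 7.48% ± 0.438. Mirlet7i (chromosome 10, 122985640 to 122985724) took 7.17% ± 1.25, and Mirlet7g (chromosome 9, 106178840 to 106178927, in an intron of Wdr82) 6.28% ± 1.13. In both animals Mirlet7b was above Mirlet7i and Mirlet7i above Mirlet7g (6.69, 6.29 and 5.48% in animal 1, 8.78, 8.06 and 7.08% in animal 2). Only the place of Mir139 among these 4 changed: it was highest in animal 1, at 7.17% (95% interval 7.15 to 7.20), and below Mirlet7b and Mirlet7i in animal 2, at 7.79% (7.76 to 7.83). The 10 most abundant genes held 48.8% ± 5.25 of the counted reads and the 25 most abundant 70.2% ± 1.38.

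Below these, Mir127 (4.44% ± 0.120), Mir770 (3.93% ± 0.367) and Mir487b (3.77% ± 0.510) came from the Dlk1-Dio3 region. Mir744, in an intron of the kinase gene Map2k4, held 3.39% ± 0.367. Mir99a held 2.38% ± 0.265. Mir99b (1.88% ± 0.443), Mirlet7e (2.17% ± 0.0932) and Mir125a (1.20% ± 0.705) lie within the same stretch of chromosome 17, from 17830188 to 17830879, in introns and an exon of Spaca6. Mir149, in an intron of Gpc1, held 1.88% ± 1.09. Mir652, in an intron of Tmem164 on the X chromosome, held 1.72% ± 0.146. Mir23b (1.29% ± 0.416), Mir298 (1.27% ± 0.166), Mir30d (1.24% ± 0.367), Mir324 (0.952% ± 0.0950) and Mir22 (0.879% ± 0.824) complete the most abundant genes, by mean CPM, outside the lists below. Some of these means join unlike values: Mir22 held 1.46% in animal 1 and 0.296% in animal 2, Mir149 2.65% and 1.11%, and Mir125a 1.70% and 0.700%.

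In all, 307 of the 2202 genes reached 10 CPM in both libraries, 92 reached 1000 CPM in both, and 770 had a read in at least 1 library. The number detected depended on the threshold, with 517 genes at 1 CPM and 198 at 100 CPM.

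The imprinted Dlk1-Dio3 region, whose microRNAs are made from the maternal chromosome in mouse, held 21.7% of counted reads in animal 1 (95% interval 21.7 to 21.8) and 22.2% in animal 2 (22.1 to 22.2), a mean of 22.0% ± 0.316. Of its 51 listed members, 47 were detected, against 12.1% of all other microRNA genes (Fisher's exact test, adjusted p = 7.0e-36). Most members lie in clusters of 14 and 39 genes and are not independent, so this p-value overstates the evidence. Mir127 (109592846 to 109592915) and Mir433 (109591715 to 109591838) lie opposite an exon of Rtl1, Mir770 (109563692 to 109563785) lies in an exon of Meg3, and Mir487b (109727333 to 109727414) is annotated between genes. Mir382 (109733771 to 109733846), in an exon of Mirg, held 1.58% ± 0.272.

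**Figure D1:**
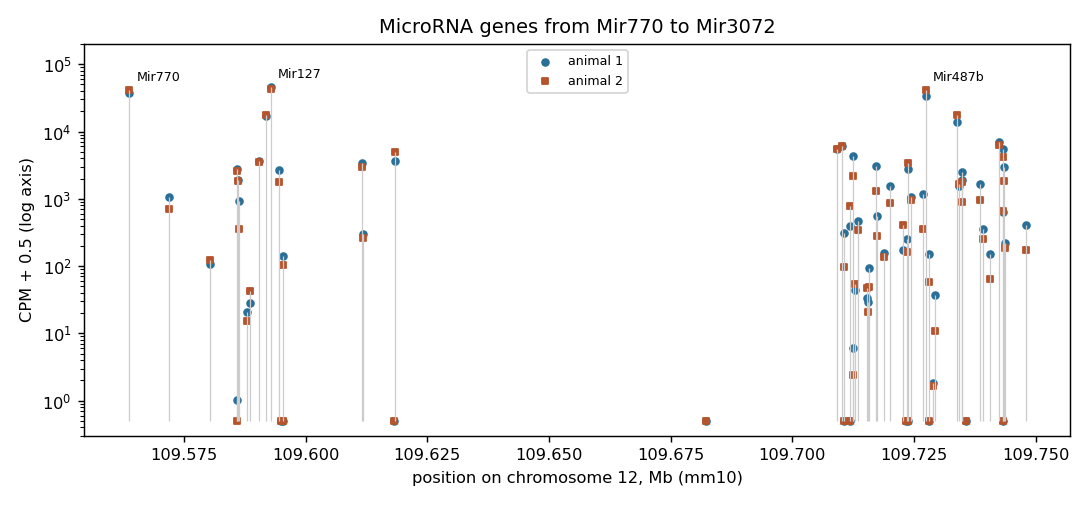
CPM + 0.5 on a log axis (y) of every microRNA gene from Mir770 to Mir3072 against its position on chromosome 12 in Mb (x, mm10); circles are animal 1 and squares animal 2, and points at the bottom had no read. The 65 genes fall into separate stretches, and Mir770, Mir127 and Mir487b are the highest, at means of 3.93%, 4.44% and 3.77% of counted reads.

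The let-7 family, known to rise as the brain matures, was detected in all 12 of its members (Fisher's exact test, adjusted p = 4.2e-10). It held 22.5% of counted reads in animal 1 (95% interval 22.4 to 22.5) and 28.7% in animal 2 (28.7 to 28.8), a mean of 25.6% ± 4.42. By symbol, 6 of the 12 members have other copies, so the family share and the order among its members are uncertain. After TMM, all 12 members were higher in animal 2 by the exact binomial test, and also 12 when adjusted over the list alone. Mirlet7b was 1.51-fold higher in animal 2, Mirlet7i 1.48-fold, Mirlet7g 1.49-fold, Mirlet7e 1.22-fold and Mirlet7d 1.66-fold. Log2 ratios in the family ran from -0.97 (Mirlet7f-1) to -0.07 (Mirlet7f-2). With library totals only, Mirlet7f-2 was higher in animal 1, Mirlet7e and the others kept their sign, and 10 of the 12 were higher in animal 2 by the test. In the unstranded column Mirlet7e had no count, as it overlaps an antisense gene, and could not be compared.

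**Figure D2:**
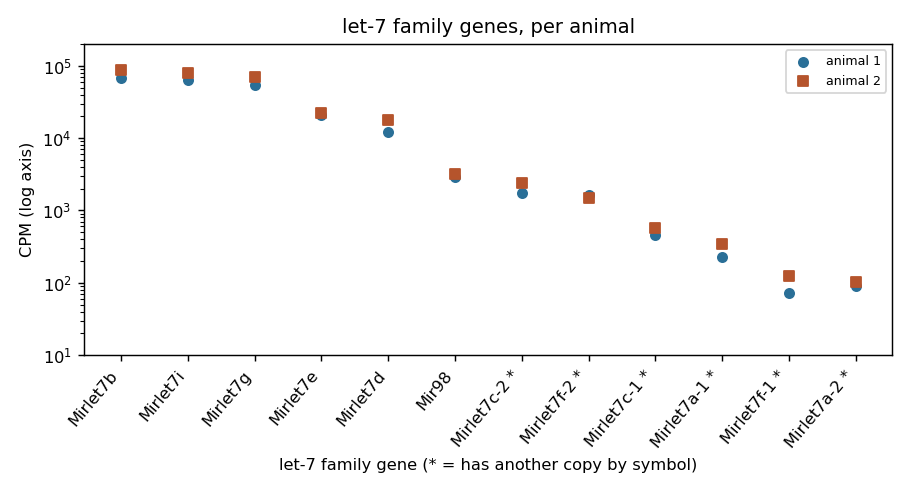
CPM on a log axis (y) of the 12 let-7 family genes (x), circles for animal 1 and squares for animal 2; an asterisk marks a gene with another copy by symbol. The 6 genes with another copy are the lowest, below the 6 without.

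Neuron-enriched microRNAs held 4.80% (95% interval 4.78 to 4.82) and 4.75% (4.72 to 4.78) of counted reads in animals 1 and 2, a mean of 4.78% ± 0.0371. Of the 39 listed genes 22 were detected, or 56.4%, against 13.2% of all other microRNA genes (adjusted p = 2.6e-09, Fisher's exact test). The share detected was larger for the blood and microglial list (71.4%) and the epithelial list (62.5%), so the test does not single out neurons. Among the neuron-enriched genes, Mir128-1, in an intron of R3hdm1, led at 1.62% ± 0.130. Mir137 held 0.858% ± 0.0983, Mir132, whose transcription follows neuronal activity, 0.675% ± 0.0319, and Mir128-2, in an intron of Arpp21, 0.585% ± 0.0310. Mir128-1 and Mir128-2 are copies by symbol, so the level of each is uncertain. Of 27 members tested, 8 were higher in animal 1 and 7 in animal 2, 15 when adjusted over the list alone. These numbers depended on the scaling: 14 and 4 with library totals only, and 6 and 8 with DESeq2 size factors.

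Mir9 and Mir124, the best known microRNAs of neural precursors and neurons, had few counted reads. Mir9-3 had 333 reads in animal 1 and 438 in animal 2, Mir9-1 had 131 and 68, and Mir9-2 had 15 and 7. Mir124a-1 had 13 and 7 reads, Mir124a-2 had 7 and 1, and Mir124a-3 had 4 and 2. All of these have several genomic copies, and reads mapped to several positions stand in a row apart from the genes. The levels of these microRNAs are therefore uncertain and may be too low. The 141 multi-copy genes by symbol held 4.31% ± 0.0727 of counted reads. Of them 39 were detected, at a median of 129.8 CPM, while 268 of the 2061 other genes were detected, at a median of 354 CPM. Reads mapped to several positions were 1.27 times as many as those counted in animal 1 and 1.33 times in animal 2.

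Glial, vascular and blood microRNAs were measured as other cell types of the tissue. Of the oligodendrocyte-enriched genes 2 of 5 were detected (adjusted p = 0.197, Fisher's exact test), with 0.141% ± 0.0322 of reads. Mir219a-2 stood at 769.9 CPM ± 288 and Mir338 at 633 ± 45.6, while Mir219a-1, at 10.9 ± 13.2 (20.2 in animal 1 and 1.54 in animal 2), and Mir3065, at 0.768 ± 1.09 (0 and 4 reads), were low. Mir219a-2 was higher in animal 2 (log2 ratio -0.98, 95% interval -1.07 to -0.90), as was Mir338, and Mir219a-1 was higher in animal 1. Mir219a-1 and Mir219a-2 are copies by symbol, and Mir219a-1 had 77 and 4 reads in animals 1 and 2, so their opposite directions are uncertain. Endothelial Mir126a, in an exon of Egfl7, held 2.89% of counted reads in animal 1 (95% interval 2.87 to 2.91) and 0.826% in animal 2 (0.816 to 0.838), a log2 ratio of 1.60 (95% interval 1.58 to 1.62). Its partner Mir126b had no count, which allows up to 0.788 and 1.15 CPM. Over both animals the endothelial list held 1.86% ± 1.46, and its detection had an adjusted p of 0.308 by Fisher's exact test. In the unstranded column, reads of Mir126a, Mir219a-2, Mir338 and Mir219a-1 were ambiguous with an antisense gene, so the endothelial share fell to 5.7e-05% and the oligodendrocyte share to 0%. Smooth muscle and pericyte genes went the other way: Mir143 (0.353% ± 0.0737, log2 ratio -0.63, interval -0.67 to -0.59) and Mir145a (0.0309% ± 0.0237, or 0.0141 and 0.0477% in animals 1 and 2, -1.96, -2.11 to -1.81) were higher in animal 2; the list held 0.383% ± 0.0975 (adjusted p = 0.111 for detection, Fisher's exact test).

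Blood and microglial microRNAs held 0.177% ± 0.0250, with 5 of 7 detected (adjusted p = 0.0023, Fisher's exact test), and 4 of 6 tested were higher in animal 2 (3 with library totals only). Mir150 stood at 814 CPM ± 199.9, Mir146 at 773 ± 24.0, Mir142 at 101.9 ± 20.4 and Mir155 at 52.6 ± 1.04. Erythroid genes held 0.00638% ± 0.00223 (adjusted p = 0.558, Fisher's exact test); Mir451a (18.7 CPM ± 12.9; 27.9 and 9.60 in animals 1 and 2) and Mir144 (14.7 ± 9.34; 21.3 and 8.07), which share a transcript in red blood cells, were higher in animal 1, and Mir486 (28.9 ± 0.0619) and Mir3107 (1.56 ± 0.0281) did not pass the test. In the unstranded column Mir142, Mir486, Mir451a and Mir3107, which overlap an antisense gene, had no count, and the erythroid share was 0.00159%. Detection at 100 CPM did not pass for the blood and microglial list (adjusted p = 0.238, Fisher's exact test), and detection at 1 CPM passed for the erythroid list (adjusted p = 0.0212, Fisher's exact test).

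Tissue next to the cortex was measured by choroid plexus and ciliated cell genes, which held 0.130% ± 0.0279 (adjusted p = 0.116, Fisher's exact test). Mir204, of the choroid plexus, stood at 808 CPM ± 80.4 and did not pass the test between the libraries after TMM, while with library totals only 1 gene of the list, Mir204, was higher in animal 1. The ciliated cell genes Mir34c (277 ± 246; 102.7 and 450.6 in animals 1 and 2), Mir449a (211 ± 106; 136.4 and 286.6) and Mir34b (4.11 ± 3.96; 1.31 and 6.92) were higher in animal 2. At 1 CPM the list's detection passed (adjusted p = 0.0182, Fisher's exact test). MicroRNA genes of the Hox clusters, in a list labelled posterior Hox, held 0.00711% ± 0.00244 (adjusted p = 0.594, Fisher's exact test). That label does not describe all members: Mir10b, which led at 61.6 CPM ± 19.4, lies in an intron of Hoxd3. Mir10a stood at 6.57 ± 4.83 (3.15 and 9.99 in animals 1 and 2, higher in animal 2 by the test). Mir196b, in an exon of Hoxa9, stood at 2.01 and Mir615, in an intron of Hoxc5, at 0.970.

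Genes of other tissues were low. The epithelial list held 0.0348% ± 0.00649, with 5 of 8 detected (adjusted p = 0.0047, Fisher's exact test): Mir203 at 160.5 CPM ± 65.3, Mir375 at 109.8 ± 22.3, Mir429 at 26.4 ± 2.49 and Mir200b at 23.6 ± 18.7 (36.8 and 10.4 in animals 1 and 2; log2 ratio 1.60). Of 6 members tested, Mir200b was higher in animal 1, and Mir203 and Mir375 in animal 2. At 100 CPM this call was lost (adjusted p = 0.719, Fisher's exact test). Striated muscle genes held 0.00512% ± 0.000586 (adjusted p = 0.406, Fisher's exact test), with Mir206 at 24.4 CPM, Mir499 at 16.5, Mir208b at 6.55 and Mir208a at 3.70. Mir122, of liver, stood at 42.2 CPM ± 0.486 (adjusted p = 0.197, Fisher's exact test). Pluripotent cell genes held 0.000764% ± 0.000115 (adjusted p = 0.304, Fisher's exact test), with Mir302d at 3.37 CPM and Mir302a at 2.86; Mir302b and Mir292 stood at 0.516 and 0.576 CPM, from 1 and 2 reads and from 0 and 3, and Mir292 had no count in the unstranded column. The testis X cluster held 0.00102% ± 2.75e-05 (adjusted p = 0.163, Fisher's exact test); Mir547 stood at 7.97 CPM, and Mir741, Mir470 and Mir743b had 3, 4 and 3 reads in 1 library each. None of the 14 pluripotent and 21 testis genes was detected at 10 CPM in both libraries.

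Clusters tied to growth and maturation were also measured. The mir-17-92 cluster and its paralogs, active in proliferating precursors, held 0.833% ± 0.0501, with 8 of 15 detected (adjusted p = 0.0012, Fisher's exact test). Mir17 stood at 2907 CPM ± 620.2, Mir93 at 2843 ± 575.4, Mir92-1 at 918 ± 382 and Mir20a at 634 ± 104.7. The mir-29 family, known to rise in the maturing brain, was detected in 4 of 4 members at 0.139% ± 0.0439 (adjusted p = 0.0012, Fisher's exact test). Its 3 members Mir29a (1089 CPM ± 351.5), Mir29c (243 ± 69.8) and Mir29b-2 (29.0 ± 14.4; 39.1 and 18.8 in animals 1 and 2) were higher in animal 1, and Mir29b-1 (25.6 ± 3.58) did not pass the test. At 100 CPM the family's detection did not pass (adjusted p = 0.102, Fisher's exact test). The mir-181 family held 1.39% ± 0.0387, with 5 of 6 detected (adjusted p = 0.0012, Fisher's exact test). By counted reads it was led by Mir181d (5712 CPM ± 571.7), Mir181b-2 (3797 ± 226.1), Mir181c (3163 ± 1131) and Mir181a-1 (1197 ± 2.70). Mir181b-2, Mir181a-1, Mir29b-1, Mir29b-2 and Mir92-1 have other copies by symbol, so their levels and their order among single-copy members are uncertain. The Sfmbt2 list takes all Mir297, Mir466, Mir467 and Mir669 genes, most of which lie in the rodent Sfmbt2 cluster on chromosome 2. It held 0.183% ± 0.0144, with 6 of 81 detected (adjusted p = 0.163 by Fisher's exact test, and 0.0048 at 1 CPM, below other genes). Of the 81 genes 43 are multi-copy, and 0 of these were detected, so the low detection is uncertain. Mir467d stood at 853 CPM ± 170.9, Mir669c at 368 ± 9.03, Mir467e at 290.5 ± 4.30 and Mir669o at 166.5 ± 27.4.

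**Figure D3:**
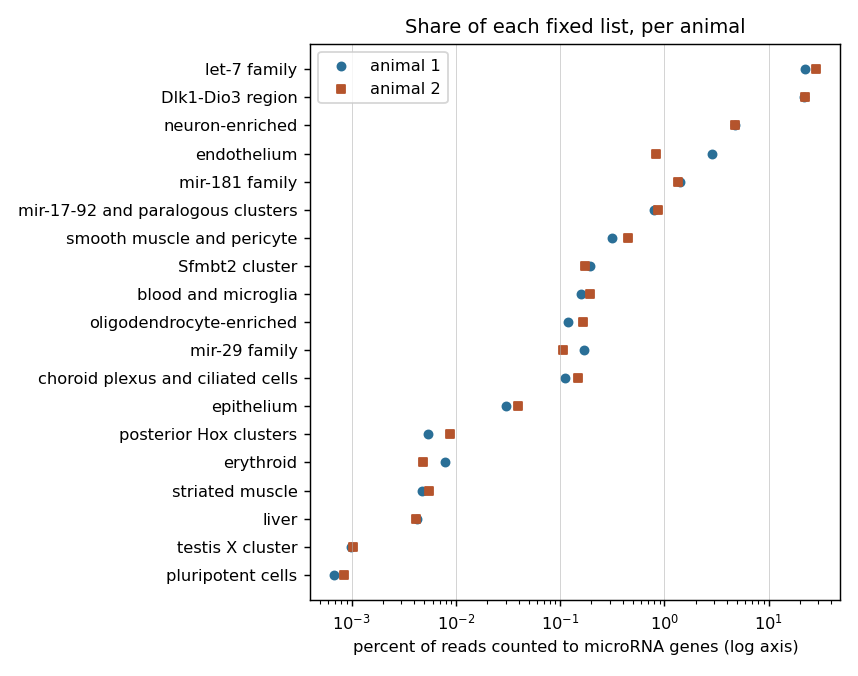
Percent of reads counted to microRNA genes, on a log axis (x), taken by each of the 19 fixed lists (y), with circles for animal 1 and squares for animal 2. The let-7 family and the Dlk1-Dio3 region lie highest, at means of 25.6% and 22.0%, and the endothelial list lies farthest apart on this plot among lists above 1%, at 2.89% and 0.826%.

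Across genes the 2 libraries ranked microRNAs alike: over 531 genes Pearson's r was 0.976 (95% bootstrap interval over genes 0.971 to 0.980) and Spearman's rho 0.956 (0.941 to 0.966). These correlations run across genes, which are not independent replicates. The common biological coefficient of variation was 38.0%. The libraries were not the same library deposited again: a chi-square test of their counts gave 198073 with 530 degrees of freedom.

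By the exact binomial test, 274 of 531 genes differed between the 2 libraries beyond counting noise, 143 higher in animal 1 and 131 in animal 2. Of these, 90 differed at least 2-fold, 69 higher in animal 1 and 21 in animal 2. With library totals only, 67.5% of the calls were higher in animal 1, against 52.2% with TMM; with DESeq2 size factors 128 were higher in animal 1 and 146 in animal 2, or 46.7%. The genes highest in animal 1 relative to animal 2 were Mir301 (log2 ratio 3.46, 95% interval 3.25 to 3.69; 3364 and 181 reads), Mir181a-2 (3.15, 2.53 to 3.92), Mir195a (2.82, 2.75 to 2.90), Mir340 (2.32, 2.10 to 2.56) and Mir214 (2.20, 1.94 to 2.47). Those highest in animal 2 relative to animal 1 were Mir26a-1 (-3.20, -3.87 to -2.63), Mir34c (-2.34, -2.51 to -2.17), Mir669e (-2.04, -2.68 to -1.47), Mir145a (-1.96, -2.11 to -1.81) and Mir140 (-1.82, -1.87 to -1.76). Mir181a-2 and Mir26a-1 have other copies by symbol, Mir669e shares a run of bases with another hairpin, and these 3 rest on few reads (306 and 20, 27 and 150, and 34 and 84). In the Dlk1-Dio3 region 22 of 48 tested members were higher in animal 1 and 20 in animal 2, 42 when adjusted over the list alone. With library totals only these were 30 and 10, and with DESeq2 size factors 21 and 22. Adjusted over the list alone, 8 members of the mir-17-92 list were called against 7 over all genes, 7 of the Sfmbt2 list against 6, and the other 17 lists had the same number of calls.

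**Figure D4:**
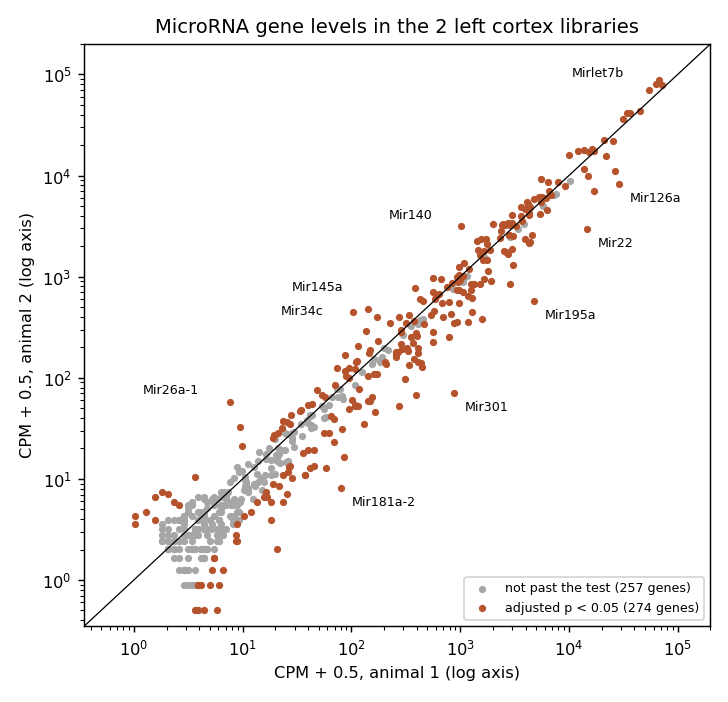
CPM + 0.5 of 531 microRNA genes in animal 1 (x) and animal 2 (y), both on log axes, with the line of equal values. Genes past the exact binomial test are coloured (274) and the rest grey; Mir301, Mir195a, Mir22 and Mir126a lie below the line and Mir26a-1, Mir34c and Mir140 above it.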

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

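All tests in this part were chosen after the results were seen, and several replaced earlier forms, whose outcomes are given. The flagged values come from data outside the comparisons above: reads on the strand opposite a gene, and reads that fit several positions. Of opposite-strand reads, 99.95% in animal 1 and 99.94% in animal 2 lay on genes that overlap another microRNA gene. Away from those, 4 genes had more than 3 opposite-strand reads in both libraries: Mir3083 with 38 and 32, Mir5620 with 15 and 17, Mir7654 with 8 and 12, and Mir8105 with 7 and 4 reads in animals 1 and 2. These 4 genes were chosen after their values were seen. The own-strand reads were 33 and 29 for Mir3083, 26 and 18 for Mir5620, 0 and 2 for Mir7654, and 0 and 0 for Mir8105. Reads placed at several positions made up 42.74% of all reads in animal 1 and 40.39% in animal 2.

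Detected multi-copy genes had a median of 129.8 CPM, against 354 CPM for other detected genes, although a larger share of them was detected (27.7% against 13.0%). With copies defined by a shared run of bases that share was smaller instead, at 6.26% against 21.4%, and the medians were 225 and 396 CPM. A candidate explanation is that reads fitting several copies were left uncounted: in 17 of 21 clusters that hold both kinds, multi-copy members lay below their single-copy neighbours on the same strand (exact sign test, two-sided, p = 0.0072; 1 further cluster tied). Over the same clusters the neighbours were higher by a median of 3.95 on the log2 scale (sign-flip permutation p = 0.00357). That value rests on the same differences as the sign test and is no separate support. Clusters here are named genes on the same strand with gaps of at most 10000 bases and at least 1 detected member. They include those of Mir9-1 and Mir124a-1. Whether cluster members share a transcript was not tested. Low transcription is argued against only where they do, and differences in how hairpins are cut stay open. An earlier test, of whether these neighbours differ from other detected single-copy genes, did not pass (permutation p = 0.137; medians 838 and 339 CPM). For Mir9 and Mir124a the 6 genes have 2 single-copy neighbours, at a median of 53.9 CPM, so uncounted reads and low transcription cannot be told apart.

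Genes differed between the 2 animals. A linear trend with GC content of the whole hairpin is argued against, as removing it left an SD of 0.816 from 0.821. GC content of the sequenced 5′ and 3′ arms was not examined, so a bias by the sequence of the reads stays open. A lower share of neurons in 1 library cannot be told apart from other causes. Over the 6 lists of endothelium, smooth muscle and pericytes, blood and microglia, erythroid cells, choroid plexus and ciliated cells, and oligodendrocytes, a difference between lists did not pass with cluster means as units (permutation p = 0.195) and lay just under 0.05 with genes as units (permutation p = 0.0493), which counts genes of a cluster as independent. Earlier forms of this test left out oligodendrocytes and passed (permutation p = 0.0461 and 0.00737), so its outcome depends on the lists and units chosen. Levels of the primary transcripts cannot be told apart from other causes: clusters shared part of the difference (SD of log2 ratios within clusters 0.708, and 0.795 over the same 134 genes, permutation p = 0.0095), and no repeat library shows how much of the rest is technical; an earlier form set the 0.708 against 0.109 from counting noise, which decides nothing here. Counting noise here leaves out duplicates of amplification, and a difference in library preparation or in single cell types stays open and was not tested, as does a biological difference between the animals.

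All 12 let-7 genes were higher in animal 2 after TMM, and 11 of them by sign with library totals only, Mirlet7f-2 excepted. Levels of the primary transcripts cannot be told apart from other causes. At 3 loci with a neighbour of another family, the let-7 gene lay below it in 4 of 4 pairs. The differences were -0.39, -0.58, -0.57 and -1.37 on the log2 scale (median -0.58). In size, 3 of these are smaller than the SD of a difference between 2 genes within clusters in general, 1.00. An earlier form compared the intervals, which lay apart in all 4 pairs but cover counting error only. The other 9 let-7 genes have no such neighbour. A family-wide difference in cutting or stability, or in how let-7 sequences entered the libraries, was not tested and stays open.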

How the results depend on the processing

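The alternatives for multi-copy genes and the region-wide definition of Dlk1-Dio3 were chosen after seeing the data; the rest were planned. Most of the 177 alternative values kept their side or stayed within the spread; the exceptions follow. The common coefficient of variation from edgeR lay between 37.7% and 40.6%. The median over genes of the DESeq2 dispersions, a different measure, gave 45.1%. The number of genes differing lay between 238 and 280. All of these were within 1.5 times the main values. No animal could be left out of these 2 results or of the correlations, which need both. Each animal alone stays within 1 SD of a mean of 2 by construction, so those values say nothing of stability.

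Detected genes numbered 517 at 1 CPM, 198 at 100 CPM and 527 at 3 counts. At 1 CPM, detection over other genes became significant for the erythroid (56.6 points, Fisher's exact test, adjusted p = 0.0212) and choroid plexus (48.1, p = 0.0182) lists. By the same exact test, detection under other genes became significant for the Sfmbt2 list (-14.1, adjusted p = 0.0048). Of the 81 genes of that list 43 are multi-copy, so their detection is uncertain. At 100 CPM detection over other genes lost significance by the same exact test for blood and microglia (19.6, adjusted p = 0.238), epithelium (3.52, p = 0.719) and mir-29 (41.1, p = 0.102). Pearson's r was 0.982 with a pseudocount of 2 and 0.966 at 100 counts, and rho was 0.931 at 1 count; the cause was not tested.

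Unstranded counts drop genes with an antisense partner, Mir126a among them. Shares became 5.05% neuron, 0% oligodendrocyte, 5.7e-05% endothelium, 0.00159% erythroid, 0.00455% liver, 0.00110% testis X, 22.4% Dlk1-Dio3, 0.897% mir-17-92, 1.502% mir-181 and 4.44% multi-copy. With all reads as the denominator every share fell, since that denominator is larger: 2.46% for the most abundant gene, 15.5% for the top 10, 1.53% neuron, 0.0449% oligodendrocyte, 0.122% smooth muscle, 0.0564% blood and microglia, 0.00207% erythroid, 0.0414% choroid plexus, 0.0110% epithelium, 0.00163% striated muscle, 0.00135% liver, 0.00225% posterior Hox, 0.000243% pluripotent, 0.000325% testis X, 7.02% Dlk1-Dio3, 8.14% let-7, 0.266% mir-17-92, 0.0448% mir-29, 0.447% mir-181, 0.0588% Sfmbt2 and 1.38% multi-copy; the endothelial share stayed within its SD. Without Mirlet7b they were 5.18% neuron, 0.00458% liver, 0.00110% testis X, 23.8% Dlk1-Dio3, 19.4% let-7, 0.904% mir-17-92, 1.51% mir-181, 0.199% Sfmbt2 and 4.67% multi-copy. Multi-copy genes by a shared run of 20 bases held 12.2%.

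Library totals only shifted log2 ratios by 0.20 towards animal 1 and moved the split of calls to 189 and 91. The 10 genes named for their ratios kept direction and call under every alternative that could test them. They were picked for extreme ratios in these same counts, and the alternatives moved the ratios little. With library totals only, the ratio of Mir140 went from -1.82 to -1.61. Their agreement therefore says little of stability. Depth sets the limit for a count of 0, at 0.788 CPM in animal 1 and 1.15 CPM in animal 2.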

Other observations

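Chromosome 12 held 23.0% ± 0.122 (SD, n = 2) of counted reads, with 58 of its 146 microRNA genes detected. Chromosome 15 held 10.1% ± 1.28, chromosome 7 8.92% ± 0.286, chromosome 9 8.88% ± 1.12, and the X chromosome 4.30% ± 0.389, with 29 of 142 genes detected. None of the 6 genes annotated on the Y chromosome had a read in these female animals. By position, hairpins in introns of the same strand held 43.8% ± 0.455 of reads, those in exons 33.4% ± 0.126, and those between genes 13.7% ± 0.142.

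Several clusters outside the fixed lists were abundant, and they were chosen after their values were seen. Mir296 and Mir298, on chromosome 2 from 174267047 to 174267585, held 2.01% and 1.61% in animals 1 and 2. Mir191 and Mir425, on chromosome 9, held 0.859% and 0.904%. The 3 genes Mir23b, Mir27b and Mir24-1 held 1.11% and 1.68%, and their relatives Mir23a, Mir27a and Mir24-2 held 0.561% and 0.938%, with the larger share in animal 2 for both. Mir497 and Mir195a, neighbours on chromosome 11, held 0.598% in animal 1 and 0.142% in animal 2.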
